A study of Mus musculus with 6 samples.

How the data were processed

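Libraries were made from total RNA with the QuantSeq 3' mRNA-Seq FWD kit, which reads a tag near the 3' end of each transcript, per the labels' protocols. The deposited values are raw read counts per gene, made with featureCounts 2.0.0, per the file headers. Exons were summed by gene identifier on the Ensembl release 104 annotation of GRCm39, with 1 file per sample and no normalization. The command names neither a strand option nor multi-mapping reads, so counting was unstranded and reads with more than 1 alignment were left out by default, per the file headers. Reads of a gene and an overlapping or antisense partner can therefore not be told apart, and copies of near-identical genes lose reads. STAR, FastQC and DESeq2 are named without a role, per the submitters' processing notes; the version of STAR is not given in the sources used here, nor are molecular identifiers mentioned. A tag count does not depend on transcript length, so no length correction was applied.

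From these counts, genes kept by filterByExpr (12833 of 55416) were scaled by TMM in edgeR 4.0.16 under R 4.3.3 and tested with glmQLFit (robust) and glmQLFTest, two-sided, cKO against control with 3 samples each and no covariate. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM of single genes and lists were counts scaled to the total of all counts in a library, without TMM. A fold against a group at 0 was computed over the pooled counts of each group with a limit of 3 counts, and a ratio with 1 to 3 counts in a group was given an exact 95% interval, both covering counting error only. Gene symbols came from a table of gene identifiers, which gave a symbol for 52083 of 55416, and biotypes from GENCODE M21 by identifier; coordinates were those of the deposited files. Overlap with other genes was computed from the exon coordinates of the files, over all exons and over the last 500 bases.

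Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and adjustment over the tested lists, beside an estimated correlation and fry. The main tests, 33 lists, alternatives and naming rule were set before the data were examined. The rule named Ift88, the genes past the threshold filled to 6 per direction by unadjusted p (leaving out predicted models and pseudogenes), the 2 members of each list with the smallest p, and 10 genes of the processes in the series title; some genes it selects are not reported here. Rpl27a-ps1, Hox genes and other genes of the marker lists given as counts fall outside it and were chosen after their values were seen. A gene was called detected at 20 counts or more, a level also set after the data were seen.

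Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of 5 CPM in 3 samples, the replicate number as a block, leaving out each library, protein-coding genes, leaving out mitochondrial and ribosomal protein genes, an adjusted p of 0.10 and glmTreat against 1.2-fold. Added after the data were seen were voom with sample quality weights, counts divided by the upper mode of each library, and thinning to an equal total count. The upper mode, the most frequent count among genes with at least 20, lay between 250 and 468 counts. Lists of Hox, forebrain and choroid plexus genes were added at the same stage and are described in the closing section.

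The edgeR test was checked on simulated counts with 200 changed genes. With the estimated dispersion of all 6 libraries it recovered 0 of 100 genes at 4-fold and 0 of 100 at 16-fold with 0 false calls among 12833 genes. Without cKO replicate 2 it recovered 11 and 43 of 100 with 9 false calls among 14562 genes. With a dispersion of 0.05 it recovered 100 of 100 at each fold in all 6 libraries with 16 false calls, and without cKO replicate 2 it recovered 99 and 100 of 100 with 6. Camera recovered 10 of 10 lists of 25 genes changed 4-fold in each of these 4 simulations. Of 10 unchanged lists, 2 were called at low dispersion without cKO replicate 2 and 0 in the others. Genes were simulated independently, all members of a changed list moved up together, and only the preset correlation was used. These results therefore do not cover lists of correlated genes, lists that change in mixed directions or the estimated correlation. Figures were drawn with matplotlib 3.10.9.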

Results

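According to the labels, gene expression was measured in oligodendrocyte precursor cells isolated from mouse cortex at postnatal day 11. These cells are the dividing progenitors of the myelin-forming cells of the brain. In 3 samples, named Ift88 cKO here, both copies of Ift88 were floxed in mice carrying Cre under the Pdgfra promoter and a Rosa EYFP reporter. In the other 3 samples, named Ift88 control, 1 copy of Ift88 was wild type. Ift88 encodes an intraflagellar transport protein needed to build the primary cilium, the antenna-like organelle through which Hedgehog signals are received. Each sample pooled cells of 4 to 6 mice, so p-values measure the spread between pools. The files held raw read counts for 55416 genes from libraries primed at the 3' end of polyadenylated RNA.

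Depth was even in 5 of the 6 libraries and low in 1. Total counts were 13652035, 12756650 and 13568156 in control replicates 1 to 3 and 13909236, 568509 and 11773548 in cKO replicates 1 to 3. In the 5 deeper libraries, 14047 to 16252 genes had a count, against 3651 in cKO replicate 2. When the deeper libraries were thinned to 568509 counts they still held 11015 to 13432 genes. Ttr, which encodes the thyroid hormone carrier transthyretin and is abundant in choroid plexus, was the top gene of cKO replicate 2 with 4.59% of its counts. A count of 0 allowed a level of up to 0.216 to 0.255 CPM (the usual scaling of counts to the library total) in the deeper libraries and up to 5.28 CPM in cKO replicate 2. These limits cover counting error only, since reads copied by PCR are not independent molecules.

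**Figure D1:**
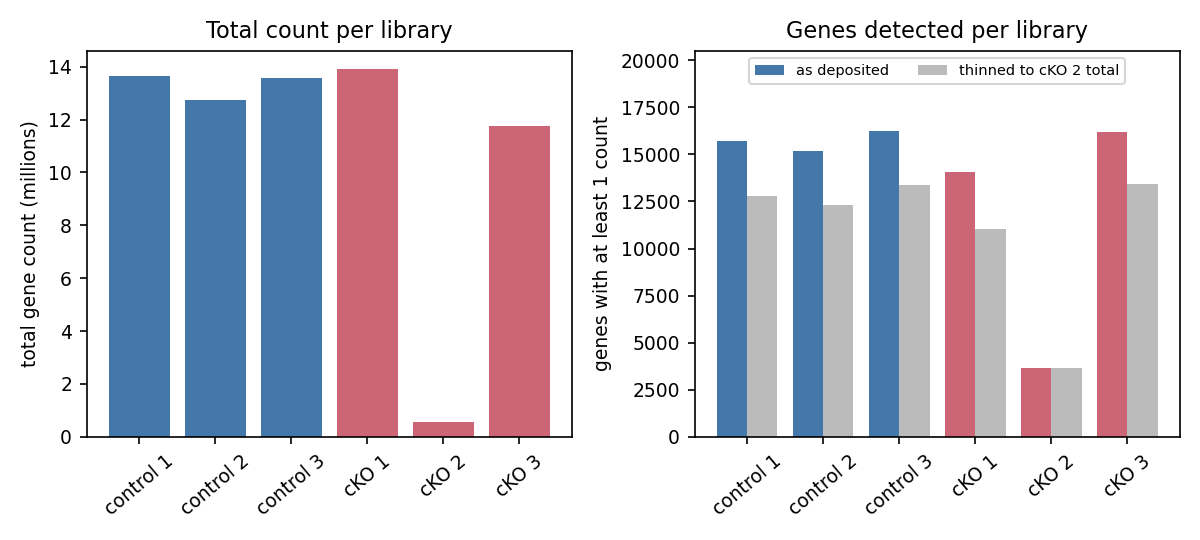
The left panel shows the total gene count of each library, and the right panel the number of genes with at least 1 count, as deposited (blue for Ift88 control, red for Ift88 cKO) and after thinning every library to the total of cKO replicate 2 (grey). At the common total of 568509 counts, cKO replicate 2 held 3651 genes and the other 5 libraries held 11015 to 13432.

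Several of the best known genes of oligodendrocyte precursors were at or near 0 counts in both groups, although 14 to 18 of 26 precursor markers had at least 20 counts in each of the 5 deeper libraries. Sox10, a lineage transcription factor, and Tnr, Pcdh15 and Rlbp1 had 0 counts in all 6 libraries. So did genes that dividing or respiring cells use widely, among them mt-Co2, mt-Co3 and mt-Atp6 of the respiratory chain, Fen1 of DNA replication and Fdps and Idi1 of sterol synthesis, so a count of 0 does not by itself show absence. Olig1 and Olig2, transcription factors of the same lineage, had 32 and 67 counts in cKO replicate 3 and 0 elsewhere. Pdgfra, the growth factor receptor whose promoter drove Cre, had 0, 59 and 56 counts in the controls and 155, 0 and 121 in the cKO libraries. Cspg4, which encodes the NG2 proteoglycan, had 110, 1 and 174 counts in the controls and 273, 2 and 159 in the cKO libraries. Other members of the fixed precursor list were well detected: Ptprz1 had a mean of 143 ± 81.7 CPM and C1ql1 of 174 ± 108 CPM in the controls (SD, n = 3). Of 26 precursor markers in the files, 10 had at least 20 counts in all 5 deeper libraries.

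Neuronal genes were abundant by comparison. Tubb3, a neuronal tubulin, averaged 1950 ± 936 CPM and Stmn2, a regulator of microtubules in growing axons, 1370 ± 1030 CPM in the controls (SD, n = 3). The summed level of 24 neuron markers was 6200, 5270 and 1660 CPM in the controls and 7920, 2170 and 7470 CPM in the cKO libraries, while the 26 precursor markers summed to 687, 799 and 423 CPM and to 717, 10.6 and 660 CPM. Of 30 myelin and mature oligodendrocyte markers, 13 had no count in any of the 5 deeper libraries, among them Mog, Mag and Mobp, which encode myelin proteins. Microglia markers had 13 of 18 genes without a count in these libraries and haemoglobin and red cell genes 6 of 8. Xist, the long RNA of the inactive X chromosome, had 0 counts in 5 libraries and 2 in cKO replicate 1, while the Y-linked gene Eif2s3y had 1167 to 3788 counts in the 5 deeper libraries. The labels used here do not give the sex of the mice.

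**Figure D2:**
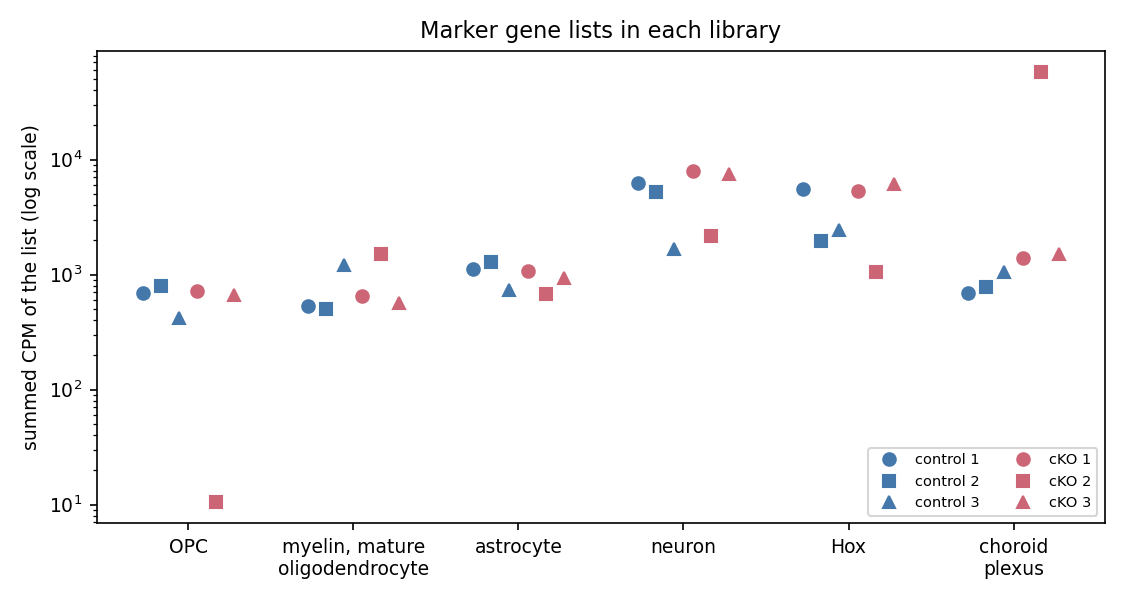
Each point is the summed level in CPM (log scale) of a gene list in a single library, blue for Ift88 control and red for Ift88 cKO, with the symbol giving the replicate number. Precursor markers lay between 423 and 799 CPM in the 5 deeper libraries and at 10.6 CPM in cKO replicate 2, whose choroid plexus genes summed to 57500 CPM against 691 to 1520 CPM elsewhere; the Hox and choroid plexus lists were chosen after the data were seen.

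The comparison of cKO with control samples asks which transcripts depend on cilia in these cells, and the series title names proliferation, Hedgehog signalling and CREB signalling. The targeted gene itself was variable. Ift88 (ENSMUSG00000040040, GRCm39 chromosome 14, 57661519 to 57755393) had 143, 32 and 167 counts in the controls and 1, 0 and 305 counts in the cKO libraries, or 8.43 ± 5.21 against 8.66 ± 14.9 CPM (SD, n = 3). Its log2 fold change was 0.05 (SE 2.20, adjusted p = 1, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The labels do not say which exons are floxed, and a 3' tag can lie outside them, so this value does not check the genotype labels. Over the alternatives its log2 fold change ran from -6.78 (without cKO replicate 3, which held 305 of the 306 cKO counts) to 0.65, and adjusted p from 0.487 to 1.

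With all 6 libraries, 1 gene was higher and 1 gene was lower in cKO samples among 12833 tested. Strip2, which encodes a component of a phosphatase and kinase complex, rose from 0 counts in every control to 169, 433 and 69 counts in the cKO libraries. Pooled over each group, the counting bound was 341-fold higher, or 123-fold without cKO replicate 2, against a limit of 3 control counts. This bound treats reads as independent molecules, which copies made by PCR are not, so the true fold can be smaller. Between control replicates, 831 to 1027 genes also had 0 counts in a library and at least 100 in another. The fitted log2 fold change of Strip2 was 14.40 (SE 2.83, adjusted p = 0.00221, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Nnat, an imprinted gene for the small membrane protein neuronatin, fell from 15396, 15460 and 2292 counts in the controls to 2, 1 and 0 counts in the cKO libraries. Its ratio of pooled CPM, control over cKO, was 7260 with a 95% counting interval of 2480 to 35200, which also treats reads as independent molecules. The fitted log2 fold change of Nnat was -12.08 (SE 1.65, adjusted p = 3.04e-09, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Strip2 lies on chromosome 6 at 29917011 to 29959680 and Nnat on chromosome 2 at 157401998 to 157404442 (GRCm39), and 17.4% of the last 500 exon bases of Nnat are shared with another annotated gene.

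Neither call passed without cKO replicate 2, although the fold changes stayed large. Without it, Nnat had a log2 fold change of -13.25 (SE 1.5, adjusted p = 0.255) and Strip2 of 9.91 (SE 3.41, adjusted p = 0.767) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, within ranges over the alternatives of 2.92e-10 to 0.891 and 1.25e-05 to 1. Strip2 also did not pass without control replicate 1, 2 or 3 (edgeR adjusted p = 1, 0.652 and 0.646). In the comparison without cKO replicate 2, 0 genes were higher and 1 of 14562 was lower: Rpl27a-ps1, a processed pseudogene of a ribosomal protein gene, with 2072, 2611 and 1710 counts in the controls and 2 in each cKO library (log2 fold change -9.92, adjusted p = 0.00992 by the same edgeR test, and adjusted p = 0.644 with all 6 libraries). Reads of a processed copy are easily assigned to a near-identical relative, so this count is uncertain. Another scaling, the RLE size factors of DESeq2 within edgeR, gave 14 higher and 2 lower genes and upper-quartile scaling gave 0 and 0, while DESeq2 itself gave 7 and 52. At an unadjusted p under 0.05 by edgeR's quasi-likelihood test the main comparison held 363 of 12833 genes, 167 of them higher and 196 lower. This is less than the share of 0.05 that would fall there with no change in any gene. Without cKO replicate 2 there were 887 of 14562, somewhat more than that share.

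**Figure D3:**
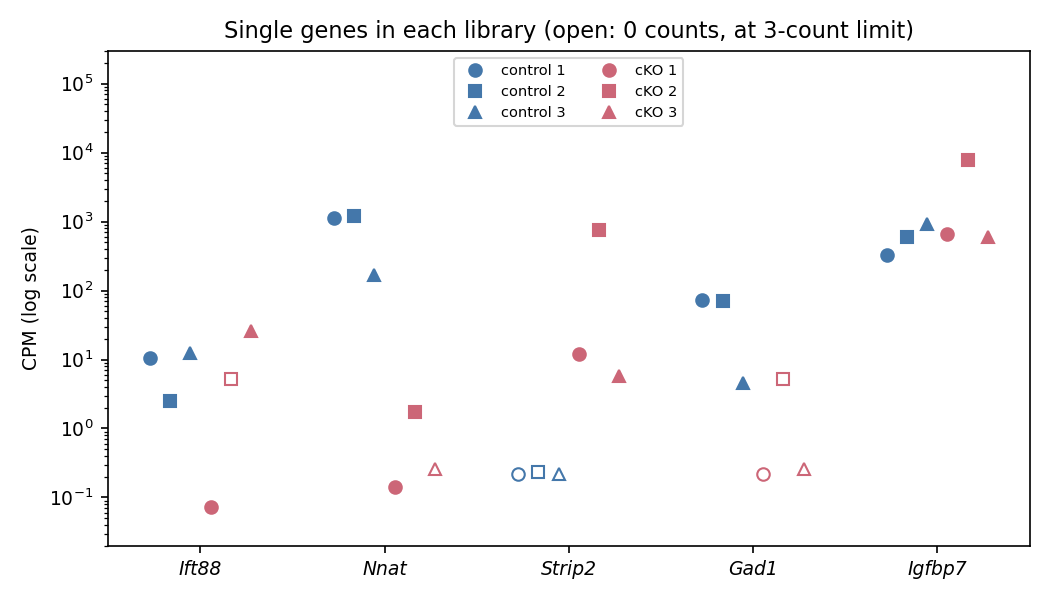
Points show the level of 5 genes in CPM (log scale) in each library, blue for Ift88 control and red for Ift88 cKO, with the symbol giving the replicate number. Open symbols mark libraries with 0 counts and are drawn at the limit of 3 counts for that library; Nnat lay at 169 to 1210 CPM in the controls and at 1.76 CPM or below in the cKO libraries, while Strip2 lay at 5.86 to 762 CPM in the cKO libraries and at 0 counts in the controls.

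The remaining genes with the smallest p did not pass the test. Igfbp7, an insulin-like growth factor binding protein, had 615 ± 299 CPM in controls and 3050 ± 4190 CPM in cKO samples (SD, n = 3), and 627 CPM on average in cKO replicates 1 and 3. The mitochondrial ribosomal RNA mt-Rnr2 had 3880 ± 1030 against 8890 ± 6310 CPM, and 5260 CPM on average in cKO replicates 1 and 3. Itpr3, Cartpt and Col9a1 had 662, 608 and 607 counts in cKO replicate 2 and at most 161 counts in any other library. In the other direction, Gad1, the enzyme that makes the neurotransmitter GABA, had 992, 901 and 61 control counts and 0 in all cKO libraries. Over the pooled groups its counting bound was 428-fold lower (adjusted p = 0.228, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Eva1c and Reck were likewise at 0 in the cKO libraries, with counting bounds of 223-fold and 213-fold lower over the pooled groups. These bounds too treat reads as independent molecules. Vim, an intermediate filament gene of glia and progenitors, had 4110 ± 2050 against 1370 ± 1040 CPM, or 1960 CPM without cKO replicate 2.

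None of the 30 testable gene lists, of 33 fixed before the data were examined, shifted between the groups by camera after adjustment. The lowest adjusted p was 0.0878 with the preset correlation, 0.828 with an estimated correlation and 0.859 by limma's fry. Unadjusted p under 0.05 was reached by 7 lists with the preset correlation and by 0 with an estimated correlation or by fry (1 in the test for changes in either direction). No list held a gene that passed over all genes tested, and adjusted over the list alone only Gad1 of the neuron markers passed, lower in cKO samples. For 15 lists the median and mean fold change and the camera direction did not share a sign.

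No gene of the cilium lists passed the test. The 29 intraflagellar transport genes other than Ift88 summed to 981 ± 71.0 CPM in controls and 1300 ± 107 CPM in cKO samples (SD, n = 3). The small cKO spread hides a difference in make-up. In cKO replicate 2 the sum of 1390 CPM was mostly Ift27 (711 CPM) and Ift57 (661 CPM), the 2 of 29 genes detected there. The sums were 1180 and 1330 CPM in cKO replicates 1 and 3. Of 26 genes tested, 0 passed (camera adjusted p = 0.706). Ift27 had 284, 420 and 175 counts in controls and 448, 404 and 184 in cKO libraries, and Ift80 had 550, 455 and 263 against 39, 0 and 261. Ciliary membrane and transition zone genes had 0 of 22 tested members past the test (camera adjusted p = 0.707). Adcy3, the ciliary adenylyl cyclase, had 424, 516 and 508 counts in controls and 104, 0 and 159 counts in cKO libraries. This was 36.3 ± 4.80 against 6.99 ± 6.77 CPM (SD, n = 3), or 10.5 CPM without cKO replicate 2. In Adcy3, 100% of the last 500 exon bases are shared with another annotated gene. Pkd1, which encodes the ciliary protein polycystin 1, had 12, 0 and 19 against 175, 0 and 43 counts and likewise shares 100% of these bases.

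Hedgehog target genes could be followed only in part. Gli1, the most widely used readout of the pathway, had 0 counts in all 6 libraries, and 5 of the 14 targets had no count in any of the 5 deeper libraries. The receptor gene Ptch1 had 10.6 ± 2.28 CPM in controls and 5.59 ± 9.54 CPM in cKO samples, or 8.39 CPM without cKO replicate 2 (SD, n = 3; adjusted p = 1, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ccnd1, the G1 cyclin, had 39.4 ± 22.2 against 169 ± 210 CPM, or 47.2 CPM without cKO replicate 2, and 100% of its last 500 exon bases are shared with another gene. Cdk6 had 48, 109 and 290 against 0, 0 and 47 counts. None of 8 tested targets passed (camera adjusted p = 0.707), nor did any of 10 tested pathway components (0.606). Gas1, a Hedgehog co-receptor, had 97, 46 and 107 counts in controls and 584, 0 and 616 in cKO libraries, and the kinase gene Gsk3b had 103 ± 24.5 against 277 ± 79.9 CPM (n = 3), or 300 CPM without cKO replicate 2.

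Targets and components of cAMP and CREB signalling did not pass either. None of 21 CREB targets (camera adjusted p = 0.729) and none of 29 pathway components (0.476) passed. Fos, an immediate early gene induced through CREB, had 203 ± 104 CPM in controls and 102 ± 88.9 CPM in cKO samples, with 0 counts in cKO replicate 2 and 153 CPM without it. Crem, a CREB family member, had 28.5 ± 8.70 against 28.6 ± 29.1 CPM (SD, n = 3), also with 0 counts in that library and 42.8 CPM without it. Fosl2 had 75, 168 and 1792 counts in controls and 0, 0 and 11 in cKO libraries, and the neuropeptide gene Sst 415 ± 481 against 51.9 ± 40.9 CPM, or 75.2 CPM without cKO replicate 2. Adcy2, an adenylyl cyclase, had 1404, 975 and 429 against 6241, 0 and 3859 counts. Immediate early genes, which respond to cell dissociation as well, had 0 of 23 tested members past the test (camera adjusted p = 0.0878). With the preset correlation the list was lower without control replicate 1 (camera adjusted p = 0.0156) and without cKO replicate 1 (0.039), in a range of 0.0156 to 0.997 over the alternatives. With an estimated correlation its camera adjusted p was 0.997 in all 6 libraries and 0.684 without cKO replicate 2. Zfp36 had 118, 292 and 304 counts in controls against 0, 0 and 27.

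No gene of the proliferation lists passed the test. Mki67, the standard marker of cycling cells, had 0 counts in all 6 libraries, and Top2a, the mitotic topoisomerase, had 35.2 ± 25.6 CPM in controls and 25 ± 26.3 CPM in cKO samples (SD, n = 3), or 37.5 CPM on average without cKO replicate 2. Genes of mitosis passed in 0 of 25 cases and genes of G1/S and DNA replication in 0 of 24 (camera adjusted p = 0.706 for each). Kif20a had 59, 173 and 549 counts in controls and 0 in the cKO libraries, with its last 500 exon bases shared with another gene, and Hells had 430 counts in cKO replicate 2 and at most 143 elsewhere. Tpx2, a spindle assembly factor, had 100, 294 and 647 counts in controls and 0, 0 and 44 in cKO libraries, and the replication gene Cdc45 had 0, 636 and 454 counts in controls and 0, 0 and 49 in cKO libraries.

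Along the lineage, 0 of 15 tested precursor markers, 0 of 17 markers of committed precursors and 0 of 13 myelin markers passed, with camera adjusted p of 0.940, 0.882 and 0.498. C1ql1 had 1256, 3784 and 1825 counts in controls and 282, 1 and 343 in cKO libraries, a log2 fold change of -3.34 (SE 1.85, adjusted p = 1, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Mbp, which encodes myelin basic protein, had 59 counts in control replicate 1 and 0 elsewhere. Nxph1 had 1614, 761 and 59 counts in controls and 217, 2 and 568 in cKO libraries, and Arpc1b, a subunit of an actin nucleating complex, 66, 125 and 1001 against 3, 0 and 112, with 48.2% of its last 500 exon bases shared. Strn, Mal and Tspan2 had 429, 334 and 164 counts in the shallow cKO replicate 2, which put their cKO means at 272 ± 418, 217 ± 321 and 101 ± 162 CPM, against 29.2 ± 7.93, 19.1 ± 13 and 15.4 ± 10.3 CPM in the controls (SD, n = 3). Without that library the cKO means of Strn, Mal and Tspan2 were 30.3, 31.6 and 7.35 CPM.

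Markers of other cells did not pass as lists but differed between single libraries. Camera adjusted p was 0.0878 for astrocyte, 0.940 for neuron, 0.922 for endothelial, 0.994 for pericyte and smooth muscle, 0.208 for fibroblast and leptomeningeal, and 0.0878 for ependymal markers. The last list holds Ttr, with 343, 94 and 2 counts in the controls and 5224, 26120 and 6756 in the cKO libraries. The astrocyte genes Aldh1l1 and Mlc1 had 93 to 244 and 77 to 108 counts in the controls and 0 in the cKO libraries, and Aldh1l1 shares 49% of its last 500 exon bases. Reln, which encodes the secreted protein reelin, had 2199, 747 and 322 counts in controls and 12229, 0 and 7617 in cKO libraries. The motile cilium gene Pifo had 300, 295 and 77 counts against 0, 195 and 0. Acta2, the smooth muscle actin, had 1690 ± 781 CPM in controls and 904 ± 242 CPM in cKO samples, and Igfbp2 1400 ± 284 against 723 ± 190 CPM (SD, n = 3), or 1030 and 832 CPM in cKO replicates 1 and 3. Ndufa4l2 had 341, 358 and 0 counts against 54, 0 and 0, and the matrix gene Dcn 143, 0 and 83 against 1974, 0 and 361. The endothelial junction gene Cldn5 had 312, 27 and 109 counts against 307, 0 and 798, and Kdr, a receptor for vascular endothelial growth factor, 446, 0 and 99 against 0, 0 and 194. Microglia, macrophage and haemoglobin lists had too few measured members for the test, with Bpgm at 22 ± 15.4 against 17.6 ± 15.3 CPM (n = 3), or 26.4 CPM without cKO replicate 2.

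Among quality measures, mitochondrially encoded genes gave a camera adjusted p of 0.0878, ribosomal protein genes 0.729 and sex-linked genes 0.707. The respiratory chain genes mt-Nd4 and mt-Cytb had 304 ± 62.8 and 342 ± 126 CPM in controls and 718 ± 444 and 758 ± 313 CPM in cKO samples (SD, n = 3), or 462 and 582 CPM without cKO replicate 2. The ribosomal protein gene Rps3 had 4860 ± 332 CPM in controls and 2940 ± 854 CPM in cKO samples, or 3170 CPM without cKO replicate 2. The Y-linked genes Ddx3y and Kdm5d had 1147, 355 and 1603 and 0, 0 and 130 counts in controls, against 730, 0 and 336 and 503, 1 and 124.

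Other signalling and stress lists were also short of the threshold. Camera adjusted p was 0.606 for Wnt targets, 0.204 for BMP and TGF-beta targets, 0.606 for Notch targets, 0.882 for ERK feedback genes and 0.204 for p53 targets. It was 0.940 for cholesterol synthesis, 0.498 for the interferon response, 0.729 for the unfolded protein response and 0.157 for hypoxia and glycolysis. The Wnt target Apcdd1 had 677, 473 and 459 counts in controls and 4790, 1 and 2832 in cKO libraries, the BMP target Msx2 1, 3 and 140 against 857, 0 and 741, and the glucose transporter gene Slc2a1 3622, 4413 and 2507 against 802, 0 and 739. Ldha, which encodes a subunit of lactate dehydrogenase, had 957, 1442 and 229 counts against 207, 0 and 78, the Wnt feedback gene Nkd1 24, 0 and 221 against 1, 0 and 52, and the matricellular gene Ccn1 813, 4163 and 7853 against 1232, 1 and 1127. Of the Notch list, Dtx1 had 122, 12 and 2 counts against 318, 246 and 342, and Hes5 0, 103 and 44 against 0, 0 and 37. The ERK feedback inhibitor Spry1 had 115, 279 and 171 counts against 3, 0 and 79, and Etv1 139, 0 and 73 against 571, 0 and 375.

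No gene of the stress and metabolic lists passed the test. The cell cycle inhibitor Cdkn1a had 311, 238 and 352 counts in controls and 461, 300 and 1 in cKO libraries, and Ccng1 2410, 2593 and 7309 against 1206, 0 and 1583. Ddit3, a transcription factor of the stress response, had 1039, 272 and 117 counts against 0, 0 and 108, and Sdf2l1 14, 264 and 211 against 350, 112 and 316. The sterol isomerase gene Ebp had 196, 556 and 373 counts against 168, 0 and 151. The interferon-induced genes Ifi35 and Mx2 had 0, 0 and 72 and 0, 47 and 271 counts in controls, against 176, 0 and 73 and 99, 0 and 0.

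Leaving out cKO replicate 2 moved 6 lists above and 3 below the other genes by camera with the preset correlation, and 0 with an estimated correlation. The lists above were Hedgehog pathway components (camera adjusted p = 0.0187, and adjusted p = 0.636 with an estimated correlation), cAMP and CREB pathway components (0.00627, and adjusted p = 0.684), neuron markers (0.0312, and adjusted p = 0.732), mitochondrially encoded genes (0.00106, and adjusted p = 0.636), Wnt targets (0.000527, and adjusted p = 0.636) and BMP and TGF-beta targets (0.0312, and adjusted p = 0.684). Those below were astrocyte markers (camera adjusted p = 0.0246, and adjusted p = 0.684 with an estimated correlation), ribosomal protein genes (0.0011, and adjusted p = 0.684) and hypoxia and glycolysis genes (0.00106, and adjusted p = 0.684). Over the 11 alternatives, adjusted p ranged up to 0.859 for the astrocyte and mitochondrially encoded lists and up to 0.997 for the other 7, and its lowest value was the one without cKO replicate 2 except for astrocyte markers (0.0136). With the preset correlation, leaving out control replicate 3 called astrocyte (camera adjusted p = 0.0136) and hypoxia and glycolysis genes (0.0483) lower. The same setting called Wnt (camera adjusted p = 0.0221), BMP and TGF-beta (0.0434) and fibroblast lists (0.0434, range 0.0434 to 0.997) higher. Leaving out cKO replicate 1, also with the preset correlation, called microglia (camera adjusted p = 0.039) and ependymal markers (0.0353, range 0.0353 to 0.881) higher. Adjusted over the list alone, 7 lists held at least 1 gene past the threshold without cKO replicate 2, 6 genes among the neuron markers, and no list gene passed over all genes tested.

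Without cKO replicate 2, 7 of the 79 tested genes selected for naming had a log2 fold change of the other sign: Itpr3, Hells, Tspan2, Pifo, Bpgm, Cdkn1a and Top2a. The spread between replicates limits the tests of single genes. Common dispersion was 1.79 with all 6 libraries and 1.32 without cKO replicate 2, and on simulated data with the dispersion of all 6 libraries the test recovered 0 of 100 genes changed 4-fold and 0 of 100 changed 16-fold.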

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

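The alternatives chosen after the data were seen were voom with sample quality weights, division by the upper mode and thinning. Higher genes, 1 in the main comparison, numbered 14 with RLE, 0 with upper-quartile scaling, 7 with DESeq2, 6 with limma-voom, 22 with no low-count filter, 2 with the stricter filter, 3 with quality weights and 0 after thinning. Lower genes, 1 in the main comparison, numbered 2 with RLE, 0 with upper-quartile scaling, 52 with DESeq2, 2 with limma-voom, 0 with quality weights and 0 after division by the upper mode. With the replicate number as a block there were 0 higher and 1 lower. Deviations of same-numbered libraries correlated at 0.011 to 0.079 across genes and those of other pairs at -0.068 to 0.013. Of 6 libraries, 5 correlated best with their own number. The numbers were not used as pairs because a correlation of 0.1 was required in every same-numbered pair, so a weak pairing stays possible. Leaving out each library gave 0 to 6 higher genes and 0 to 6 lists higher, and 0 to 3 lists lower; the lower gene count stayed at 1, but without cKO replicate 2 the gene was another. The stricter filter gave 1 list higher, ependymal markers (camera adjusted p = 0.0427 with the preset correlation). With an estimated correlation the main comparison gave this list a camera adjusted p of 0.828. Its sum of 46300 CPM in cKO replicate 2 was mostly Ttr, at 45900 CPM. Of the alternatives applied to single genes, which leave out protein-coding genes alone, glmTreat, an adjusted p of 0.10 and the 3 chosen after the data were seen, Strip2 passed in 6 of 13 with an adjusted p and Nnat in 11 of 14. Ift88 passed in 0 of 14. Over single genes, 1064 values kept their side of the threshold, 29 of them with another sign, 11 lost a call and 14 gained one; over lists, 312 kept it, 57 with another sign, and 18 gained a call. The median log2 fold change of all genes was -0.44 with TMM, -0.28 with RLE, -0.01 with upper-quartile scaling, -0.75 with limma-voom, -1.23 with the block and -0.06 without cKO replicate 2, so small shifts have no fixed direction. Except for the effect of leaving out libraries, the cause was not tested.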

Other observations

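The lists, count limits and tests of this part were chosen after the data were seen; only the splits of the samples were planned. The 5 deeper libraries expressed Hox genes, which set position along the trunk and hindbrain and are silent in the developing forebrain. Of 39 Hox genes in the files, 19 had at least 20 counts in each of these libraries, led by Hoxb8 with 36801, 5399 and 10610 counts in controls and 25329, 589 and 16141 in cKO libraries, and by Hoxa5 with 444 ± 41.4 CPM in controls (SD, n = 3). A further 10 Hox genes, among them Hoxa10, Hoxc11 and Hoxd10, had no count in any deeper library. Of 16 forebrain regional genes, 2 to 5 had at least 20 counts in each deeper library and 0 in all of them, with sums of 21.7 to 368 CPM. By camera with 3 added lists, Hox genes gave an adjusted p of 0.0599 (0.642 with an estimated correlation), forebrain genes 0.00334 (0.0816) and choroid plexus genes 1.26e-17 (0.00667), each toward cKO. Without cKO replicate 2 the values were 6.96e-05 (0.151), 0.126 (0.326) and 7.11e-05 (0.0731), and since the lists were picked from these libraries they are not independent evidence.

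Without cKO replicate 2, several Hox and patterning genes had small unadjusted p in edgeR's quasi-likelihood test and none passed after Benjamini-Hochberg adjustment; with all 6 libraries adjusted p was 1 for Hoxc4, Hoxb5, Sox11 and Gfap. Hoxc4 had 2558, 2345 and 1365 counts in controls and 10094 and 10584 in cKO replicates 1 and 3 (adjusted p = 0.444), and Hoxb5 had 3362, 2502 and 1811 against 9204 and 11253 (adjusted p = 0.448). Evx1, a homeobox gene of the neural tube, had 0 counts in every control and 284 and 850 in these cKO libraries (adjusted p = 0.512). Sox11, a transcription factor of immature neurons, had 843, 581 and 705 against 2540 and 3301 (adjusted p = 0.444), and Gfap, the astrocyte filament gene, 1825, 3585 and 3298 against 619 and 230 (adjusted p = 0.662). Between control replicates, 831 to 1027 genes had 0 counts in a library and at least 100 in another.

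The Hox genes stood beside few or no counts of Sox10, Olig1 and Olig2, and the loss of Ift88 is argued against as the cause, since the lowest control library had 1940 CPM of Hox genes. A small admixture of another cell type predicted summed Hox CPM below that of the fixed precursor list in every deeper library. Summed Hox CPM was 2.43 to 9.23 times that of the list, above this prediction but short of the bound for excluding an admixture. Summed CPM of unlike lists does not measure shares of cells, so a small admixture stays open. Against Pdgfra, Cspg4, Olig1, Olig2 and Sox10 alone, summed Hox CPM was 145 to 693 times as high. These genes were chosen after their low counts were seen, and widely used genes such as Fen1 also had 0 counts. RNA from material other than cortical oligodendrocyte precursors or an exchange of samples stays open. Of the 26 precursor markers, 20 had at least 20 counts in a control library, and other cells express some of them.

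cKO replicate 2 held 3651 genes, and read depth alone is argued against, since the deeper libraries thinned to its total kept at least 11015. Few starting molecules, each read many times, may account for the few genes. cKO replicate 2 had 3.74 genes with at least 200 and under 500 counts per gene with at least 5 and under 20, against at most 0.0845 in the thinned libraries. Thinning itself moves genes from the higher range to the lower, so this contrast cannot decide. As deposited, the deeper libraries had 2.94 to 3.53, so many reads per molecule would be common to all 6 libraries, and the number of genes reached by them is what was small in this library. RNA of choroid plexus cells stays open. In this library 6 of 14 choroid plexus genes had at least 20 counts, against 4 to 12 in the deeper libraries. That number cannot decide, since cKO replicate 2 reached few genes of any kind. Its choroid plexus genes summed to 57500 CPM against 691 to 1520 CPM elsewhere, with Ttr at 45900 CPM and Igfbp7 at 7880 CPM. Sostdc1, Otx2, Trpm3 and Enpp2 had 271 to 930 counts, while Folr1, Kl and Clic6 had 0. The labels used here do not say how the cells were isolated.

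In all, 42 genes had at least 100 counts in every control and at most 5 in cKO replicates 1 and 3, and 37 genes the reverse; other divisions of the 5 deeper libraries into 3 and 2 gave at most 59 in both directions, against 79, so loss of single genes from libraries of few molecules stays open. Of the 42 genes, 14 were pseudogenes (33.3%), the highest share in that direction, against at most 28.6% (4 of 14) in the other 9 divisions. In the opposite direction these reached 33.3% (8 of 24) and 50% (2 of 4), so a strain variant between the groups against the reference stays open too. Rpl27a-ps1 had 2072, 2611 and 1710 counts in controls and 2 in each cKO library, while its parent Rpl27a had 613, 1037 and 411 against 480, 0 and 713 and gained no counts of that size. Since reads with more than 1 alignment were left out, the lack of a gain in Rpl27a does not decide about a strain variant. The Ift88 genotype follows the same division of the libraries and stays open, untested.

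The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 2 genes and the highest other gave 5, with 7 of 10 splits at 2 or more. For the fixed lists the real split gave 0 and the highest other gave 9, in the split that put cKO replicate 2 with control replicates 1 and 2.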
